A study of Mus musculus with 14 samples.

How the data were processed

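RNA from 14 dishes of SCp2 mouse mammary epithelial cells was measured on Affymetrix mouse expression arrays. Per the labels' protocols, cells were grown in DMEM with 2% fetal calf serum, RNA was extracted with phenol and chloroform, and 200 ng of total RNA was used per array. Dishes were 35 mm wide and treatment lasted 3 days. Agent, density and experiment were taken from the labels of each sample, and the experiment letter, A or B, served as the replicate name.

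The deposited table holds log2 expression values made by the authors with RMA, per the submitters' processing notes, which name no version. Other steps are not given in the sources used here. The table has 45101 probe sets, and the median over the 14 arrays was 0 within 1e-06 for all 45101, a centring that is not stated and was seen in the values. Values ran from -7.18 to 6.62. The log base is likewise not stated; log2 is the base RMA gives, and folds printed here rest on it. The direction of each value is higher for more signal, as in RMA. The median of each array lay between -0.02 and 0.03. No scanner files were used here, so the signal over background of a gene is not known and genes near background could not be told from genes that did not change.

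Probe sets were named through the platform annotation. Of the 45037 that are not controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed, and only the first kind was used. Symbols were updated through the Entrez identifier for 34741 probe sets and kept as annotated for 204. This gave 18194 genes. Each gene was represented by its probe set with the largest SD over the 14 arrays, and was tested when that SD was at or above the 40th percentile of all probe sets that are not controls (0.049), which left 11812 genes. The rules fixed before the data were examined used the mean in place of the SD and a mean-dependent prior variance. A centred table holds no level, so both were replaced after the values were seen, with the percentile kept and without use of the labels. Of the 131 named genes, 84 had more than 1 probe set past the filter, and for 14 of these another probe set had the opposite sign in experiment A: Notch3, Itpr2, Rtp4, Ero1a, Npc2, Sparc, Dock5, Srebf2, Btn1a1, Adam12, Mdm2, Ctsb, Neu1 and Ctsa.

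Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over genes, threshold 0.05). The model over all 14 arrays had agent, centred log2 density, their product, and experiment as a block. It gave the MMP3 effect at the mean log2 density, the density slope per doubling of plated cells, the interaction, and the slope within each agent. Residual degrees of freedom were 9, and 2 and 4 in the fits to experiments A and B alone, planned as alternatives and made results of their own after the data were seen. Effects at single densities came from a model with a mean for each agent and density plus experiment; at 25K this sets 1 array against 1, with the spread taken from the other groups. The difference between experiments was fitted on the 12 arrays at 50K, 100K and 250K.

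The labels say that the letters mark separate experiments, so the block is part of the design. Deviations from the group means correlated on average at 0.06 between arrays of the same experiment (range -0.67 to 0.65). A shift common to the tested genes thus did not dominate these deviations. With so wide a range a smaller shift is not excluded, and the 18S control probe set was higher on every array of A than on any of B.

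The genes named were chosen by a rule fixed before the data were examined: up to 10 with the largest rise and 10 with the largest fall among those past the threshold and with the same sign in all 7 pairs, up to 4 passing members of each list with the largest change, and 10 genes given whatever their result. Where too few passed, those with the smallest p are given. Provisional symbols were counted and not named. The rule was applied to experiment A, with 3 of 3 pairs, after the data were seen. The 18 gene lists and 4 lists of cell type markers, written from general knowledge before the data were examined, hold 468 genes, of which 440 had a probe set and 357 were tested; the others are not analysed here. Camera was run with a preset correlation of 0.01 and with an estimated one on the 20 lists with at least 3 tested members, adjusted over the lists.

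On simulated data with 200 changed genes among 11812, the fit to all 14 arrays recovered 54% of genes changed by 1 on the log2 scale between agents and 89% of those changed by 2, with 5 false calls among 148. In the fit to experiment A these shares were 57% and 72%, with 5 false calls among 134. For a change of that size between 50K and 250K, the density slope recovered 63% and 89% with all arrays, and 32% and 65% in experiment A. The simulated genes were drawn independently and with the same spread on every array. Real genes were correlated and the spread differed between arrays, so these shares may not hold for the real data.

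The alternatives tried were no filter, a 60th percentile filter, centring of arrays on their median, quantile normalization, the mean of a gene's probe sets, each probe set tested, a mean-dependent prior variance, array weights, no experiment block, pairs as blocks, density as a factor, agent and experiment only, a 2-fold minimum, the subsets of experiments and densities, and each array left out in turn. No columns of other samples were in the table.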

Results

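SCp2 cells, a line of mouse mammary epithelial cells, were plated at 4 densities and kept for 3 days with or without MMP-3, a secreted protease that cuts extracellular matrix and cell surface proteins. RNA of each dish was measured on 1 Affymetrix array, 14 in all. Experiment A held 6 arrays, a control and an MMP3 dish at each of the densities labelled 50K, 100K and 250K, the cells plated per 35 mm dish. Experiment B held 8 arrays, the same design with 25K added. Each combination of agent and density was therefore measured on 1 array per experiment, and on 2 arrays in all except at 25K. Nothing in the labels says more about how dishes of an experiment were related, so the p-values measure the spread between these dishes after agent, density and experiment were fitted. The values are relative log2 expression with the median of each probe set over the 14 arrays at 0, so they give differences between arrays and no absolute level. The number of arrays limits the precision, and 11812 genes were tested.

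The arrays did not group by their labels in the same way in the 2 experiments. In experiment A the control arrays at 50K and 100K correlated across genes with r = 0.784 and the MMP3 arrays at the same densities with r = 0.782, while control 250K correlated with them at only r = 0.128 (control 50K) and 0.406 (control 100K), and most with MMP3 25K of experiment B (r = 0.771). Within experiment B the controls at 50K and 250K correlated with r = 0.83 and those at 50K and 100K with r = -0.495, and the MMP3 arrays at 25K and 100K with r = 0.533 and those at 25K and 50K with r = -0.318. Between the experiments, arrays with the same label correlated with r = 0.695 for control 100K, 0.679 for MMP3 250K and 0.488 for MMP3 50K. The same comparison gave r = -0.236 for control 50K, -0.364 for MMP3 100K and -0.606 for control 250K. Genes are not independent replicates, so these correlations describe the arrays and carry no p-value. Ifit1, an interferon-induced gene, shows the pattern on single arrays. Its relative log2 value was -2.94 ± 0.03 (SD, n = 3) in the controls of experiment A and 3.67 ± 0.73 (SD, n = 3) in the MMP3 dishes. In experiment B it was 3.71 and 4.26 on the arrays labelled control 50K and control 250K, and -2.83 and -2.97 on those labelled MMP3 25K and MMP3 100K. Over all genes these 4 of the 8 arrays of B correlated with the MMP3 effect of A against their label (r = 0.680, 0.704, -0.700 and -0.352 in that order). Because of this, the count of genes for the MMP3 effect is given within experiment A, within experiment B and over all arrays. Counts for the interaction and for single densities are given for both experiments together only. Few of the named genes have their effect in B given. Arrays of experiment B are called by their deposited labels.

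**Figure D1:**
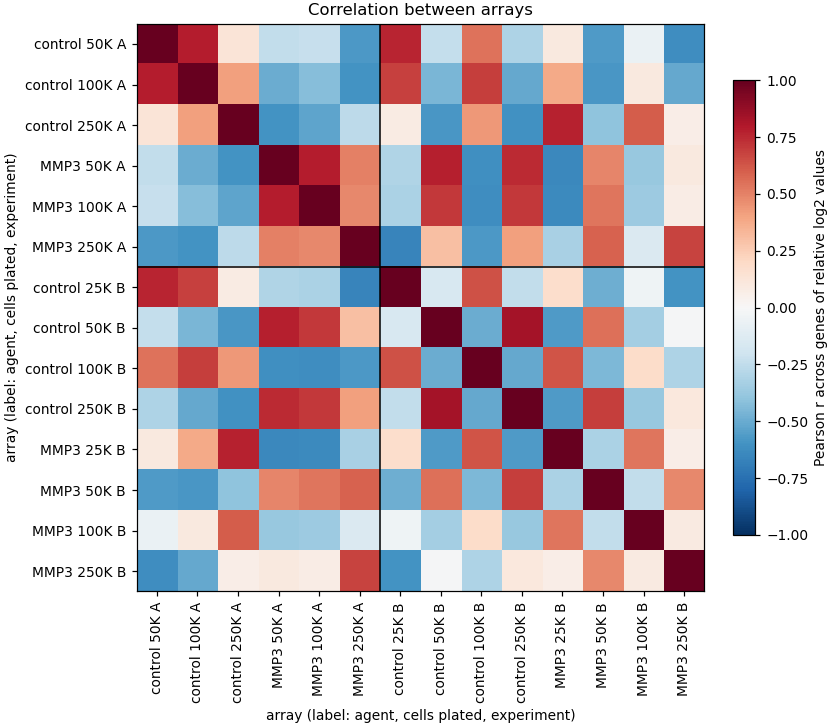
Pearson correlation across 11812 genes between each pair of the 14 arrays, on a colour scale from -1 to 1, with lines between experiment A (first 6 arrays) and experiment B (last 8). The MMP3 arrays of A at 50K and 100K correlate at r = 0.782, and control 50K of B correlates with control 50K of A at r = -0.236.

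**Figure D2:**
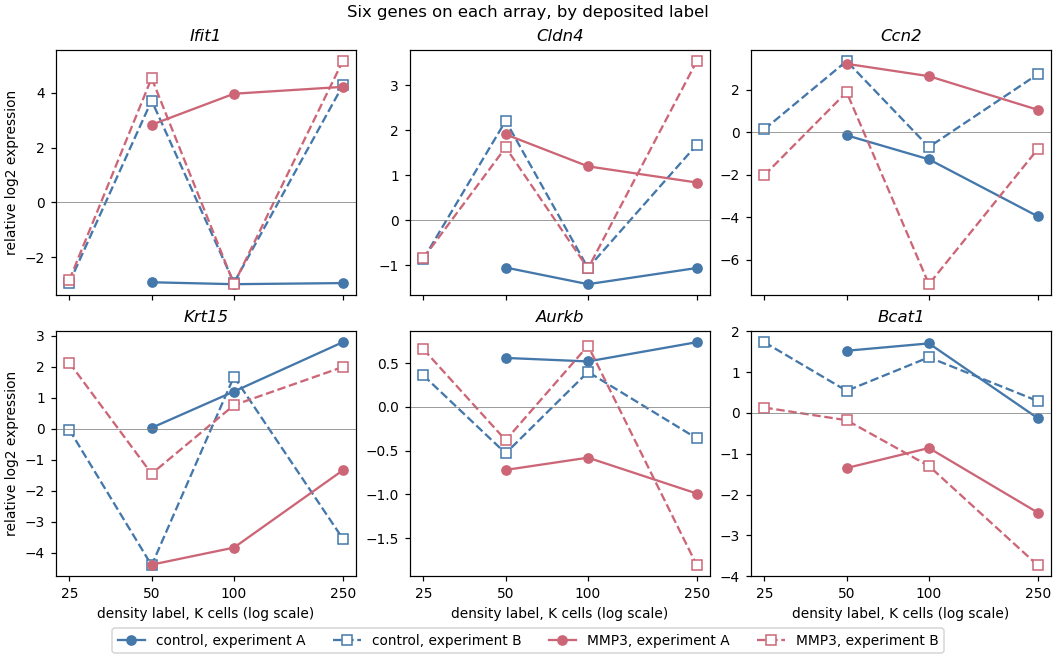
Relative log2 expression (vertical) of 6 genes against the plating density label in K cells per dish (horizontal, log scale), 1 point per array, with filled circles and solid lines for experiment A, open squares and dashed lines for experiment B, blue for control and red for MMP3. Ifit1 lies between 2.83 and 4.21 in the MMP3 dishes of A and near -2.9 in its controls, while in B it is low at 25K and 100K and high at 50K and 250K under either label; Bcat1 is lower with MMP3 at each density of both experiments.

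The main question of the design was how MMP3 changes gene expression in these cells. In experiment A the largest rises were in interferon-induced genes. Rtp4 rose by 7.03 on the log2 scale (SE 0.36), Usp18, which removes the ubiquitin-like protein ISG15 from its targets, by 6.48 (SE 0.40), and Ifit1 by 6.43 (SE 0.21), an 86.4-fold rise. Xaf1 rose by 5.03, the GTPase genes Igtp and Gbp2b by 4.88 and 4.19, and Oas1a, a sensor of double-stranded RNA, by 4.57. Adgrg1, an adhesion receptor, rose by 4.72, Ctla2a by 4.28 and St3gal5, the enzyme that makes the ganglioside GM3, by 4.18. All 10 passed with limma at adjusted p between 0.0146 and 0.0194, each with MMP3 above control in 3 of 3 pairs. The largest falls were in Rtl3 (-5.71, SE 0.16), the keratin genes Krt15 (-4.57, SE 0.29) and Krt79 (-3.34), the glutathione transferase Gsta3 (-4.16), Nrep (-3.52) and the transcription factor genes Bcl11a (-3.42) and Maf (-2.88). Plxdc1 (-3.17), Spon2 (-3.12) and Aldh1l2, a mitochondrial enzyme of folate metabolism, (-3.01) completed the 10, at adjusted p between 0.0146 and 0.0192 with limma and with 3 of 3 pairs lower. The sizes of some depend on the probe set. With the mean of a gene's probe sets the change was 3.51 for Rtp4, whose other probe set did not rise, 2.50 for Xaf1, -1.24 for Bcl11a, -0.67 for Maf, -1.57 for Spon2 and -1.70 for Plxdc1, each still past the threshold.

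Over all genes, 2425 passed adjusted p under 0.05 in experiment A with limma, 1440 higher and 985 lower with MMP3, and 820 of them changed by at least 2-fold. The fit to 6 arrays left 2 residual degrees of freedom. With any of the 6 arrays left out 1 remained, and the count was then 0. Some measures of the RNA moved with MMP3 as well in experiment A. The 3′ minus 5′ difference of the Gapdh control was -0.03 to 0.03 in the controls and 0.04 to 0.17 with MMP3. The 18S control was 0.72 to 0.81 and 0.88 to 1.07 in that order. The 3′ minus 5′ difference of the actin control overlapped, at -0.05 to 0.11 in the controls and -0.145 to 0.09 with MMP3. In experiment B all of these measures overlapped between the agents.

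The interferon response list had 18 of 27 tested members higher with MMP3 in experiment A, 20 when adjusted over the list alone, and none lower, with a median log2 change of 1.98. The list was called up with limma's camera at a preset correlation (adjusted p = 4.4e-09), and not with an estimated one (adjusted p = 0.279 with an estimated correlation). Of the list of NF-kappaB targets and chemokines, 8 of 15 rose and 1 fell (9 and 1 adjusted over the list alone), including the chemokines Ccl5 (3.61, SE 0.36) and Cxcl1 (2.14), the macrophage growth factor Csf1 (3.26) and the NF-kappaB subunit Relb (1.80). With the mean of a gene's probe sets Csf1 rose by 1.34 and Cxcl1 by 1.55, while Ccl5 and Relb were unchanged. The camera adjusted p of this list was 4.8e-04, and adjusted p = 0.279 with an estimated correlation. The macrophage markers did not move with these genes: none of 6 tested members passed and their median change was -0.05. No fibroblast (7 tested, median -0.12), endothelial (1 tested, -0.07) or adipocyte marker (2 tested, -0.03) passed either.

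Genes of epithelial junctions and identity also rose in experiment A, 15 of 29 tested with none lower (15 adjusted over the list alone). Among them were the tight junction genes Cldn4 (2.63, SE 0.17), Ocln (2.46, SE 0.12) and Marveld3 (2.14) and the polarity gene Pard6b (2.07), and the camera adjusted p was 7.8e-06 (adjusted p = 0.279 with an estimated correlation). With the mean of a gene's probe sets Marveld3 rose by only 0.70, while Cldn4 rose by 2.63, Ocln by 2.43 and Pard6b by 1.92. Cdh1, which encodes E-cadherin, rose by 0.88 (SE 0.06, adjusted p = 0.0161, limma), from -0.49 ± 0.07 to 0.40 ± 0.05 (SD, n = 3 each). Mesenchymal genes and regulators moved both ways, 3 rising and 3 falling of 17 (6 and 4 adjusted over the list alone). The repressors Snai2 (-1.50, SE 0.07) and Zeb2 (-0.83) fell, while Postn (0.99) and Sparc (0.79) rose. The list was not called by camera (adjusted p = 0.711). Vim, for vimentin, differed by 1.09 (SE 0.22, adjusted p = 0.0529, limma), Acta2 by 0.27 (adjusted p = 0.0635, limma) and Fn1 by 0.41 (adjusted p = 0.395, limma), none of which passed. Rac1, a small GTPase of cell spreading, rose by 0.54 (SE 0.06, adjusted p = 0.0241, limma), but by 0.18 with the mean of its probe sets, which did not pass (adjusted p = 0.0658, limma). Snai1, Mmp3 and Csn2 varied less over the 14 arrays than the filter required and were not tested.

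Targets of the YAP and TEAD regulators rose in 9 of 20 cases and fell in 2 in experiment A (9 and 2 adjusted over the list alone), with Ccn2 (3.88, SE 0.24), Ccn1 (3.37), Amotl2 (2.41) and Dock5 (2.36) in the lead. With the mean of a gene's probe sets Dock5 rose by only 0.79 and Ccn1 by 3.33, while Ccn2 and Amotl2 were unchanged. Of the SRF and actin cytoskeleton genes 9 of 19 rose and none fell (16 adjusted over the list alone), among them Actn1 (1.56), Cnn2 (1.21), Tpm1 (1.19) and Zyx (1.08). Basement membrane and integrin genes rose in 10 of 14 cases with none lower (12 adjusted over the list alone), including the integrin Itgb6 (1.63), the collagen IV genes Col4a1 (1.07) and Col4a2 (0.92), and Cd44 (1.06). Among matrix proteases and inhibitors 5 of 15 rose and 1 fell (8 and 1 adjusted over the list alone). Adam12 (2.78), the plasminogen activator Plau (1.90) and the inhibitor Timp2 (1.74) rose, and the gelatinase Mmp2 fell by 1.59. Camera at the preset correlation called these 4 lists up, at adjusted p = 0.0026 for YAP and TEAD targets, 7.8e-06 for SRF and actin, 7.8e-06 for basement membrane and 0.0015 for proteases. With an estimated correlation the adjusted p was 0.279 for YAP and TEAD targets, basement membrane and proteases, and 0.429 for SRF and actin.

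Some genes of cell division were lower with MMP3 in experiment A. Of the mitosis list 9 of 25 fell and none rose (15 adjusted over the list alone), with Aurkb (-1.31, SE 0.12), Cenpf (-1.09), Ttk (-0.95) and Bub1b (-0.90) as the largest falls, and of the DNA replication list 4 of 26 fell (none adjusted over the list alone) and 3 had a positive change, the 4 being Rfc4 (-0.99), Tyms (-0.83), Rfc3 (-0.79) and Rfc5 (-0.75). With the mean of its probe sets Tyms differed by -0.24 and did not pass (adjusted p = 0.150, limma). Camera gave adjusted p = 9.1e-07 for mitosis and 0.0020 for DNA replication, against adjusted p = 0.494 and 0.690 with an estimated correlation. Mki67 was 0.66 lower (SE 0.13, adjusted p = 0.0508, limma) and did not pass. Among genes of the unfolded protein and integrated stress responses 8 of 19 fell and 2 rose (9 and 3 adjusted over the list alone), with falls in Trib3 (-2.06), Vldlr (-1.80), Herpud1 (-1.32) and Ddit3 (-1.31) (camera adjusted p = 0.0311, adjusted p = 0.306 with an estimated correlation). The lysosome and autophagy list had 8 of 17 members higher and none lower (10 adjusted over the list alone), including Ctsb (2.00), Neu1 (1.85), Ctsa (0.97) and Lamp2 (0.64) (camera adjusted p = 0.0013, adjusted p = 0.279 with an estimated correlation). With the mean of a gene's probe sets these 4 rose by 0.83, 0.60, 0.48 and 0.55 in that order.

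In the other lists some members passed in experiment A. There 2425 of all 11812 genes were called, so a few called members are not particular to a list. Of the hypoxia and glycolysis genes 5 fell and 2 rose of 24, with Ndrg1 (-1.96), Ddit4 (-1.34), Pfkp (-1.25) and Pdk1 (-1.11) lower. Of the cholesterol synthesis genes 4 fell and 1 rose of 20, with Hmgcs1 (-1.41), Mvk (-0.70) and Srebf2 (-0.60) lower and Dhcr7 (0.66) higher; with the mean of its probe sets Srebf2 differed by -0.21 and did not pass (adjusted p = 0.0684, limma). Camera called this list down (adjusted p = 0.0468, adjusted p = 0.739 with an estimated correlation). Of the NRF2 genes 4 fell and 1 rose of 17, Sod2 (-0.81), Gclm (-0.63) and Gclc (-0.40) falling and Cat (0.78) rising. Basal and myoepithelial genes rose in 2 and fell in 2 of 15 cases, with Trp63 (-1.46, SE 0.18) and Krt5 (-1.05, SE 0.06) lower and Sfn (0.70) and Krt17 (0.43) higher, while Krt14 differed by -0.48 (adjusted p = 0.280, limma). Of the milk and mammary differentiation genes Btn1a1 (1.36) and Mfge8 (0.94) rose among 8. With the mean of its probe sets Btn1a1 rose by 0.44. Of the p53 targets 3 fell and 2 rose of 14, with Sesn1 (-1.06), Eda2r (-0.88), Pmaip1 (0.96) and Mdm2 (0.72). Adjusted over the list alone, the counts of risen and fallen genes were 2 and 5 for hypoxia, 3 and 10 for cholesterol, 2 and 6 for NRF2, 4 and 2 for basal, 2 and 0 for milk and 2 and 3 for p53. Camera adjusted p was 0.0612 for hypoxia, 0.104 for NRF2, 0.996 for basal, 0.457 for milk and 0.926 for p53.

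**Figure D3:**
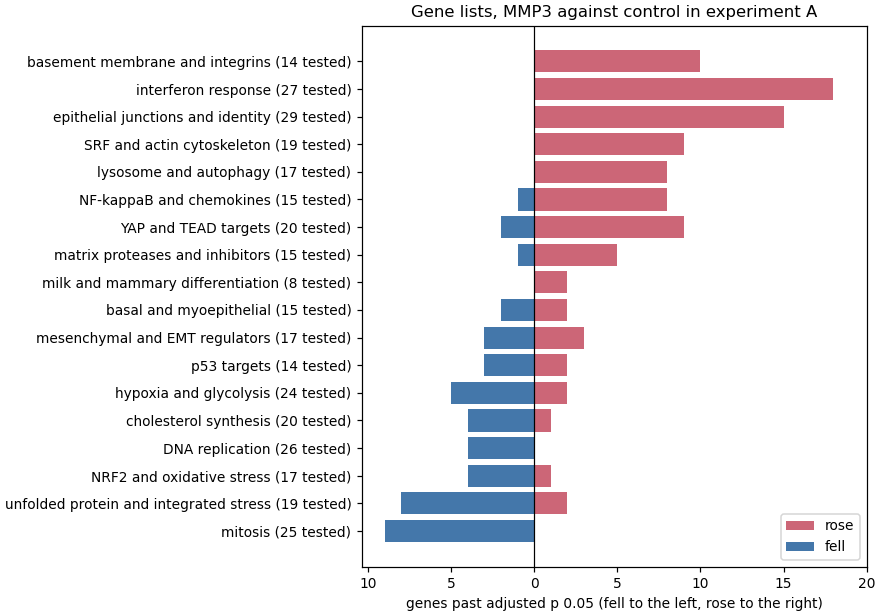
Number of genes of each of the 18 lists that passed adjusted p 0.05 for MMP3 against control in experiment A (horizontal, fallen to the left in blue and risen to the right in red), with the number tested beside each name. The interferon response list has 18 risen of 27, the basement membrane and integrin list 10 of 14, and the mitosis list 9 fallen of 25.

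In experiment B, as labelled, the same comparison gave another picture. No gene passed with limma, against 1425 at an unadjusted p under 0.05, and Ifit1 differed by 0.48 (SE 2.76, adjusted p = 0.949, limma) over its 4 pairs. Of the 2425 genes called in experiment A, 961 had the same sign in B (39.6%) and 1464 the opposite sign, with 638 opposite in all 4 pairs of B and 274 the same in all 4. Across genes the MMP3 effects of A and B correlated with r = -0.149. The sign was not stable: with each of the 14 arrays left out in turn r ran from -0.336 to 0.133, below 0 in 10 of 14 cases, and the highest value came without the array labelled MMP3 100K of B. The MMP3 effect of A correlated with the density slope of B at r = 0.718 (0.0949 to 0.810 with an array left out, lowest without MMP3 250K of B), and the density slope of A with the MMP3 effect of B at r = 0.816 (0.584 to 0.814). Each relation is across 11812 genes, which are not independent replicates.

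**Figure D4:**
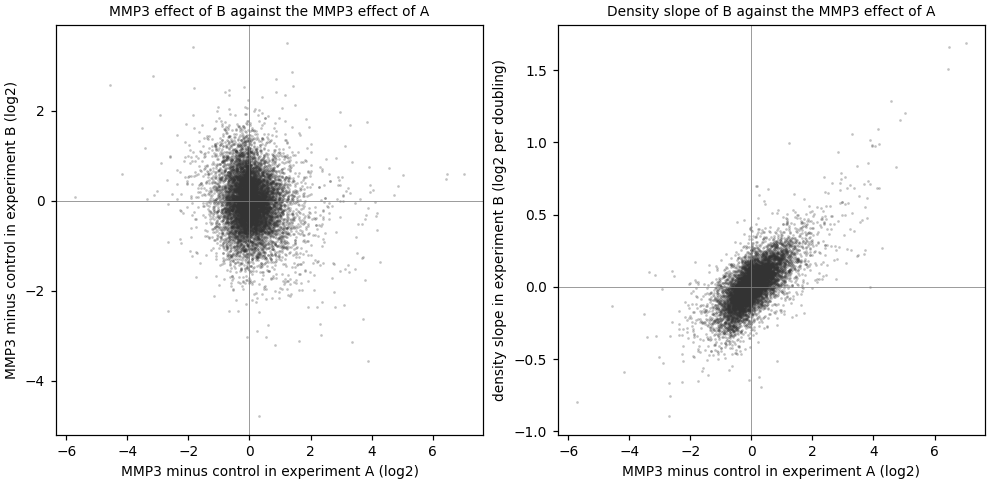
Each point is 1 of 11812 genes, with the MMP3 minus control log2 difference in experiment A on the horizontal axes and, on the vertical axes, the MMP3 minus control log2 difference in experiment B (left) and the density slope in experiment B in log2 per doubling of plated cells (right). The left cloud has r = -0.149 and the right cloud r = 0.718.

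Of the 12 lists that camera called at the preset correlation in experiment A, 6 had a median of the opposite sign in experiment B and 6 of the same sign, and no member passed in B over all genes. The opposite medians in B were -0.71 for proteases, -0.67 for SRF and actin genes, -0.46 for YAP and TEAD targets, -0.40 for NF-kappaB, -0.34 for basement membrane and -0.08 for epithelial junctions. Those of the same sign were -0.98 for DNA replication (21 of 26 fell adjusted over the list alone), 0.58 for lysosome, 0.42 for the interferon response, -0.24 for mitosis, -0.20 for cholesterol and -0.06 for the stress responses. These medians depended on the array labelled MMP3 100K, which stood apart. Without it they were -0.36 for proteases, -0.38 for SRF and actin genes, -0.32 for YAP and TEAD targets, 0.17 for epithelial junctions and 1.13 for the interferon response. The mitosis median was then -0.63, that of basement membrane -0.22 and that of NF-kappaB -0.34. The rest were -0.99 for DNA replication, 0.54 for lysosome, -0.26 for cholesterol and -0.05 for the stress responses. Of the 12, 5 were opposite. In B camera called 5 lists at the preset correlation: DNA replication (adjusted p = 4.1e-19), SRF and actin (3.1e-05) and cholesterol (0.0436) down, and lysosome (3.5e-05) and milk (0.0436) up. With an estimated correlation none was called, at adjusted p = 0.428, 0.694, 0.694, 0.490 and 0.490 in that order. The difference between the experiments in the MMP3 effect was itself tested on the 12 arrays at 50K to 250K. No gene passed with limma, and 1620 had an unadjusted p under 0.05. The plain difference between experiments gave 0 genes with limma, and 737 at an unadjusted p under 0.05.

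Over all 14 arrays, with experiment as a block, 325 genes passed for MMP3 with limma, 158 higher and 167 lower, and none when each matched pair of control and MMP3 dishes was the block. Of the 325, 283 had the same sign in 7 of 7 pairs. Ifi27l2a, an interferon-induced gene, rose by 2.52 (SE 0.51), the vitamin B12 carrier Tcn2 by 2.38 (SE 0.49) and the receptor Notch3 by 1.77 (SE 0.26). Tcp11l2 (1.73), Mindy2 (1.68), Crebrf (1.60), the calcium channel Itpr2 (1.48), the adhesion gene Nectin4 (1.46), Grina (1.42) and Ypel3 (1.38) rose as well. Bcat1, which starts the breakdown of branched-chain amino acids, fell by 2.39 (SE 0.32) and the transferrin receptor Tfrc by 1.66 (SE 0.31). Tubb3 (-1.43), Adamts5 (-1.42), Mei4 (-1.35), Fut9 (-1.14), Mtm1 (-1.10), the checkpoint kinase Chek1 (-1.09), E2f8 (-1.06) and Trip13 (-1.02) were also lower. These 20 had adjusted p between 0.0286 and 0.0475 with limma. The sizes depend on the probe set. With the mean of a gene's probe sets Bcat1 fell by 0.85, Adamts5 by 0.81 and Chek1 by 0.53, each still past the threshold. Tcn2 rose by 1.28, Notch3 by 0.91 and Itpr2 by 0.37, and these passed as well. Crebrf (1.18, adjusted p = 0.118, limma) and Mtm1 (-0.68, adjusted p = 0.0590, limma) no longer passed.

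DNA replication genes fell in 8 of 26 cases over all arrays (22 adjusted over the list alone), among them Cdc45 (-0.87, SE 0.19), Rrm2 (-0.86, SE 0.17), Mcm4 (-0.74) and Rrm1 (-0.73), with a median of -0.69 (camera adjusted p = 2.3e-18, adjusted p = 0.164 with an estimated correlation). Lysosome and autophagy genes rose in 3 of 17 cases (12 adjusted over the list alone), namely Hexa (0.61, SE 0.10), Npc2 (0.55) and Lamp2 (0.54) (camera adjusted p = 8.1e-10, adjusted p = 0.134 with an estimated correlation). In the hypoxia list Ero1a rose by 0.45. With the mean of their probe sets Rrm1 (-0.39, adjusted p = 0.0656, limma) and Ero1a (0.20, adjusted p = 0.0585, limma) did not pass. The interferon list had a median of 1.18 and the mitosis list one of -0.42 with no member passing. Camera called them at adjusted p = 1.3e-04 and 5.6e-06, with adjusted p = 0.622 and 0.485 with an estimated correlation. Camera also called the epithelial (adjusted p = 0.0417) and milk (0.0327) lists up and the cholesterol list (0.0080) down, with no member passing and adjusted p = 0.644, 0.171 and 0.485 with an estimated correlation. Of 12 other settings, the milk call was lost in 6, among them quantile normalization (adjusted p = 0.0517) and no filter (0.108), and the epithelial call was lost in 2 and in 9 of 14 fits that left out an array. Array weights and the mean-dependent prior, among the 12, did not enter camera and could not change a call. The remaining 11 lists and both marker lists with at least 3 tested members were not called. Cdh1 differed by 0.22, Vim by -0.32, Fn1 by -0.76, Acta2 by -0.49, Krt14 by -0.65, Rac1 by 0.17 and Mki67 by -0.41, with adjusted p between 0.190 and 0.844 (limma), and none passed.

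The pooled count rested on how the arrays were used. Of the 325 genes, 112 were also called in experiment A, where 2425 of all 11812 genes were called. All 112 had the same sign. The arrays of A are part of the pooled fit, so this is no independent support. Across genes the pooled MMP3 effect correlated with the MMP3 effects of A and B at r = 0.585 and 0.711. With their density slopes it correlated at r = 0.551 and 0.816. The pooled rises and falls thus hold for the deposited labels, and do not part what A gave for MMP3 from what it gave for density. Adjusted over the list alone, 0 DNA replication genes fell with MMP3 in A, 18 of 26 along its density slope and 21 with MMP3 in B. The count was 0 without the experiment block, 0 with each matched pair as a block and, among the fits that left out an array, 0 in 10 of 14, while it was 1287 without the array labelled MMP3 100K of B.

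The labels also ask what plating density does. No gene passed for the density slope with limma over all arrays, against 1358 at an unadjusted p under 0.05. The smallest p-values belonged to the mitotic genes Kntc1 (-0.27 log2 per doubling of plated cells, SE 0.04) and Cdkn3 (-0.23), to Ccsap (-0.43) and, with positive slopes, to Abca7 (0.29), Dcaf6 (0.27) and the profilin gene Pfn2 (0.32), each at adjusted p = 0.133 (limma). DNA replication genes had a median slope of -0.27 and mitosis genes -0.21, while the lysosome list had 0.16 and the interferon list 0.52, with no gene past the threshold over all genes. Adjusted over the list alone, 18 of the 26 DNA replication genes fell and 9 of the 17 lysosome genes rose. Camera called the 4 lists at adjusted p = 1.2e-21, 2.6e-09, 1.9e-09 and 1.2e-05 in that order, against adjusted p = 0.108, 0.433, 0.108 and 0.576 with an estimated correlation, and it called the epithelial list up (0.0123) and the cholesterol list down (0.0080). With an estimated correlation these had adjusted p = 0.616 and 0.459, and without a filter the cholesterol call was lost (adjusted p = 0.117).

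Within each agent the density slope passed for 0 genes with limma, with 490 genes in control cells and 1087 in MMP3 cells at an unadjusted p under 0.05. Without the array labelled MMP3 100K of B, 297 genes passed in MMP3 cells. Experiment A alone gave 0 genes for the slope with limma and 3506 at an unadjusted p under 0.05. Its DNA replication genes had a median slope of -0.32 (18 of 26 fell adjusted over the list alone), and its SRF and actin genes one of -0.19 (12 of 19 fell adjusted over the list alone). Camera called both down, at adjusted p = 3.7e-09 and 1.8e-06, against adjusted p = 0.609 and 0.585 with an estimated correlation. It also called NF-kappaB (median -0.27, adjusted p = 2.7e-04) and proteases (-0.29, 0.0480) down and lysosome up (0.20, 1.2e-04), each with adjusted p = 0.585 with an estimated correlation. The mitosis (-0.08), interferon (0.14), epithelial (0.01) and cholesterol (-0.07) lists, called over all arrays, were not called in A, at adjusted p = 0.0626, 0.0735, 0.650 and 0.128.

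Crossing the factors asks whether the MMP3 response depends on density. No gene passed for the interaction with limma, and 228 had an unadjusted p under 0.05. The smallest p-values were those of H2ax (-0.51 log2 per doubling, SE 0.10), Pimreg (-0.49), Kntc1 (-0.34), Lrrc51 (0.46), Wfdc3 (0.66) and Abhd16a (0.24), all at adjusted p = 0.9998 (limma). Camera called mitosis (median -0.33, adjusted p = 2.2e-13) and DNA replication (median -0.16, adjusted p = 1.9e-06) down and lysosome genes up (median 0.10, adjusted p = 0.0011), each with adjusted p = 0.629 with an estimated correlation. With quantile normalization the DNA replication median was -0.04 and that of lysosome genes 0.05, and neither was called (adjusted p = 0.207 for both). At single densities, MMP3 against control passed for 0 genes at 25K, 50K and 100K with limma, with 386, 213 and 1243 genes at an unadjusted p under 0.05. The count at 100K was 364 in the continuous density model, and the count at 25K was 37 without a filter. At 250K, 3 of 975 such genes passed. Brca1, a DNA repair gene, differed by -2.64 (SE 0.21), Cavin4 by 1.63 (SE 0.11) and Smim5 by 2.00 (SE 0.16), each at adjusted p = 0.0399 (limma). They are named because the count was so small, after their values were seen. None passed with the 60th percentile filter, with quantile normalization, with a mean-dependent prior or in the continuous density model, where the count was 0. Brca1 did not pass without the experiment block (adjusted p = 0.333, limma), and neither Brca1 (0.0703) nor Smim5 (0.0648) passed without the array labelled MMP3 100K of B.

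The MMP3 effect and the density slope are independent contrasts in this design, and across genes their correlation was r = 0.875 when all arrays were fitted, with a covariance of 0.04. The value depended on single arrays. It was 0.392 without control 250K of B and 0.530 without MMP3 25K of B, and at most 0.912 with another left out. With the labels shuffled among the arrays of each experiment, which keeps the correlation between genes, 99 other arrangements gave r from -0.8398 to 0.8747, against 0.8751 for the deposited one, which was the largest of the 100. Values close to it thus arose under other labels too. In 100 simulations of unchanged genes r lay between -0.05 and 0.05 with a mean covariance of 8.1e-06, but these genes were drawn independently, which makes that range too narrow for real arrays. At an unadjusted p under 0.05 in both, 599 genes were up and 559 down in both, and 0 went opposite ways. Independent lists of independent genes would share 62.5 and 55.6, while the shuffled labels gave up to 382 and 262, and no other arrangement as many in all. No gene was called in both after adjustment. Within experiment A the same correlation was -0.159, and within experiment B it was 0.376.

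The array labelled MMP3 100K of experiment B stood apart from the other 13. Its SD over probe sets was 0.869, against 0.232 to 0.412, and 1439 genes lay more than 4-fold from their median over arrays. Its lowest values included the growth factor gene Epgn (-7.18), Ccn2 (-7.14) and Sfpq (-6.48), and its highest Abcc5 (6.09), Kif14 (6.04), Txnip (5.96) and the clock gene Nr1d1 (5.47). These genes were taken for their extreme values on this array. The 3′ minus 5′ difference of the actin control was 0.65 there and at most 0.19 elsewhere, while that of the Gapdh control was -0.02, within the range of the other arrays. The medians of markers of other cell types on it were 0.02 for fibroblast, 0.08 for macrophage, 0.05 for endothelial and 0.18 for adipocyte genes. The adipocyte median lay above the highest other array (0.13). Single markers stood out: 2 of 7 fibroblast markers were at least 2-fold up, and the macrophage marker Cd68 was at 4.61.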

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

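All tests of explanations in this part were chosen after the results were seen. The MMP3 response of experiment B, as labelled, did not follow that of experiment A. Of all genes, 14.2% had their 3 pairs of A in one direction and their 4 pairs of B in the other, while 8.33% had one sign in all 7 pairs. Each share would be 1.56% if signs and pairs were independent, which was not shown, so both agreement and opposition exceed that value. Of the 20 genes named for experiment A by size, Bcl11a and Plxdc1 were opposed in this way, at -3.42 in A and 1.19 in B, and at -3.17 in A and 2.78 in B; for these genes the difference was not tested singly, and no gene passed the test of the difference over all genes.

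Leaving out the outlying array labelled MMP3 100K did not bring the missing agreement. Without it the MMP3 effects of A and B correlated at r = 0.133 across genes (SD 0.154 over arrays left out in turn). That SD is not a standard error of r, so this value alone does not exclude the array as the whole cause. Correlations between single arrays other than this one argue against it as the whole cause. Control 50K of B correlated with MMP3 50K of A at r = 0.777 and with control 50K of A at -0.236. Control 250K of B correlated with MMP3 250K of A at r = 0.413 and with control 250K of A at -0.606. Control 100K of B went with its own label (r = 0.695). Whether that array set the sign of the correlation, which was -0.149 with all arrays, cannot be told apart from the weight of other arrays, since r stayed below 0 in only 10 of the 14 fits that left out an array. A weaker response in experiment B is argued against as the whole cause. Along the MMP3 effect of A, taken from 2 pairs of A and measured on the pair held out, its 4 control arrays spanned 1.08 times the MMP3 minus control difference of A and the controls of A 0.302 times, and a weaker response would not set control dishes so far apart. Whether the response by label was weaker or absent beneath this spread cannot be told apart from an opposite one. By deposited label, its MMP3 minus control difference along the MMP3 effect of A was -0.144 times that of A. The difference was -0.146 (SE 0.397), with an SD of 0.534 among the controls and 0.589 among the MMP3 arrays, against 0.084 and 0.059 in A, whose arrays defined this axis. Labels of experiment B that belong to other arrays stay as a candidate explanation. They need arrays out of place under both agents. In B, 2 controls (50K and 250K) and 2 MMP3 arrays (25K and 100K) correlated with the MMP3 effect of A against their label. Along the held-out axis these 2 controls lay at 0.54 and 0.48, and the controls at 25K and 100K at -0.29 and -0.39. The held-out MMP3 dishes of A lay at 0.39 to 0.55. A different response to MMP3 in B would not by itself part control dishes in this way. These values argue against it as the whole cause. Other differences between the dishes of B could also give this pattern. An order of labels that alternates control and MMP3 from 25K upward, along the samples as listed, was tried. It gave r = 0.808 and 0.788 with the 2 effects of A, against -0.149 and 0.288 for the deposited order. By the sum of the 2 correlations it had rank 25 of 40320 orders, while 16871 orders (41.8%) scored above the deposited one. The alternating order was picked after these correlations were seen, so this is no test of it. A true difference between the experiments, other than in the response to MMP3 alone, was not tested apart from misplaced labels and stays open. The alternating order was not used to test single genes.

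The array labelled MMP3 100K of experiment B lay far from the other 6 MMP3 arrays on 4 measures, by a gap that exceeds Dixon's critical value. Its SD over probe sets was 0.869 (others 0.232 to 0.412), it had 1439 genes beyond 4-fold (others 35 to 156), its actin 3′ minus 5′ difference was 0.654 (others -0.145 to 0.192), and its actin 3′ value was -1.82 (others -0.360 to 0.307). Its 1439 genes also stood out among the 4 MMP3 arrays of experiment B. In all, 32 groups of values were examined and chance alone flags about 1 in 20.

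The array labelled MMP3 100K in experiment A had an SD of 0.250, inside the range of the others, so that dish did not show such a spread. As 1 array of the other experiment, it cannot tell what MMP3 at 100K did in B. The fibroblast and macrophage lists did not rise as sets. The medians of their 7 and 6 tested markers on this array were 0.0230 and 0.0800, within the range of the other arrays. Of these markers 2 and 1 were at least 2-fold up, the 1 being Cd68, at 4.61. With members that differ in this way, the medians do not exclude these cells. Endothelial cells and adipocytes stay open as well, since their lists held 1 and 2 tested genes. Their medians were 0.0466 and 0.184, the last above the highest other array (0.134). Degraded RNA cannot be told apart from other causes that would spare some transcripts, since the actin control stood out and the Gapdh control, at -0.0238, did not.

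The interferon-induced genes of experiment A had a median change of 1.98 (27 genes), while the 6 macrophage markers had a median of -0.0477 with an SD of 0.185, which argues against macrophages in the MMP3 dishes. Other immune cells were not tested. Lyz2, an abundant macrophage transcript, differed by 0.02 and Csf1r by -0.02. The Gapdh and 18S controls also moved with MMP3 in A, while the actin 3′ minus 5′ difference overlapped between the agents. Whether RNA quality had a part was not tested. What raised these genes in A was not tested further, and a response to MMP3 or to something supplied with it stays open.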

How the results depend on the processing

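Chosen after the data were seen were the SD rule and a prior variance that does not depend on the mean. The mean-dependent prior, fixed before, thereby became an alternative. Also chosen after were the doubted array left out of probe set choice or of the fits at single densities and between experiments. So were the medians of lists in B without that array and the arrays left out for the correlation below. So were the alternatives to the fits of single experiments taken as results of their own. The other alternatives, experiment A only and experiment B only among them, were chosen before. The cause of each change was not tested except where fewer arrays or genes entered. The MMP3 effect over all arrays (325 genes) was 206 without a filter, 2 with the 60th percentile filter, 686 with quantile normalization (294 up, 392 down), 644 with every probe set tested, 49 with a 2-fold minimum and 4980 with array weights, whose estimation did not converge. It was 2425 in experiment A only and 0 in experiment B only, without the 25K arrays, with density as a factor and with agent and experiment only. With regard to pairing, it was 0 with no replicate block and 0 with each matched pair as a replicate block. Leaving out an array gave 0 to 1287 genes, with 0 for 10 of 14 arrays, 622 without control 250K of A, 682 without control 50K of B, 293 without MMP3 100K of A and 1287 without MMP3 100K of B. With probe sets also chosen without that array the counts were 1368 for MMP3, 153 for the density slope and 312 for the slope in MMP3 cells. The density slope and the interaction kept a count of 0 otherwise. Leaving out an array gave 0 to 1 genes for the slope in control cells (1 without control 50K of B) and 0 to 297 for the slope in MMP3 cells (297 without MMP3 100K of B). At 25K the count of 0 became 37 without a filter, 3 with quantile normalization and 2 with no replicate block. At 100K it became 364 in the continuous density model. At 250K the 3 genes became 6 without a filter and 0 with the 60th percentile filter, with quantile normalization, with a mean-dependent prior and in the continuous density model, while 3 without the block no longer held Brca1 and 2 without MMP3 100K of B held neither Brca1 nor Smim5. In experiment A the count of 2425 became 884 without a filter and 4188 with every probe set tested, and 0 with any array left out, where 1 residual degree of freedom remained; its density slope passed for 123 genes with the 60th percentile filter. The correlation of MMP3 effect and density slope ran from 0.392 (without control 250K of B) to 0.912 with an array left out, and was 0.685 without control 250K of A and 0.530 without MMP3 25K of B. Genes not called that changed sign were Vim (0.10 with quantile normalization, 0.72 with array weights, 1.09 in A only, -0.58 to 0.0566 with an array left out and 0.10 with the doubted array out), Acta2 (0.0732 with array weights, 0.27 in A only), Fn1 (0.41 in A only), Cdh1 (-0.27 in B only) and Rac1 (-0.0844 in B only). The epithelial list had -0.0768 in B only and the interaction of the DNA replication list 0.0114 in A only. No other gene or list for which alternatives were run changed sign, but these covered only the lists called over all arrays and the named genes within the fit that named them, so the opposite effects in B of genes named for A, such as Bcl11a and Plxdc1, lie outside this statement. Calls of lists were lost as well, out of 12 settings and 14 fits with an array left out: for the MMP3 effect milk in 6 and 4, epithelial in 2 and 9, cholesterol in 1 and 1, mitosis and interferon in 1 and 0; for the slope cholesterol in 3 and 2, epithelial in 2 and 4, interferon in 2 and 1, mitosis in 1 and 0; for the interaction lysosome in 3 and 1 and DNA replication in 2 and 1. The other calls held in these settings at the preset correlation. Array weights and the mean-dependent prior, among the 12 settings, did not enter camera and could not change a call. With an estimated correlation no list was called in the main fits. Lists not called there also differed in sign between fits, such as SRF and actin (-0.11 over all arrays, 0.50 in A, -0.67 in B) and NF-kappaB (-0.02, 1.07 and -0.40). With the mean of a gene's probe sets, 11 of 28 named genes called over all arrays and 29 of 88 called in A had effects over 1.5 times smaller, the most for Itpr2 (0.37) and, in A, Maf (-0.67). None changed sign, and 4 (Crebrf, Mtm1, Rrm1 and Ero1a) and 3 (Tyms, Srebf2 and Rac1) no longer passed. Signal over background is not in the table, so what it limits could not be measured.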

Other observations

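The values of single arrays, the splits of arrays and the shuffles of density in this part were chosen after the results were seen. On single arrays of experiment B the gene lists moved widely. On the array labelled MMP3 250K, the median relative log2 value was -1.58 for DNA replication and -1.37 for mitosis genes, 2.29 for interferon-induced genes, 0.77 for lysosome genes and 0.55 for fibroblast markers. On the array labelled MMP3 100K the medians were -1.48 for matrix proteases and inhibitors, -0.98 for DNA replication, -0.83 for SRF and actin genes, -0.66 for YAP and TEAD targets and 0.70 for mitosis genes. Those values belong to 1 array each and have no replicate.

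The 18S control probe set was between 0.72 and 1.07 on the 6 arrays of experiment A and between -0.59 and 0.01 on the 8 arrays of experiment B. Within experiment A it was higher with MMP3 (0.88 to 1.07) than in the controls (0.72 to 0.81), and within experiment B the agents overlapped.

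Other splits of the arrays were counted for each result. For the MMP3 effect over all arrays, 100 splits into 7 and 7 were taken from 1716, with the real split among them. Of these, 2 gave at least the 325 genes of the labels. The splits kept neither experiment nor matched pair, so the arrays could not be exchanged freely and this share does not exclude chance. The count itself does not hold under other fits: it was 0 with each matched pair as a block, 0 without the experiment block and 0 in 10 of the 14 fits that left out an array. The highest other split gave 1078 genes, over 3 times as many, which points to a structure of the samples other than the labels. Among the 64 splits that part all 7 pairs only 1, the real one, reached 325, and the highest other gave 0. For experiment A the 10 splits are too few for a share under 0.05. The labels gave 2425 genes, reached by 1 split, and the highest other gave 0. For experiment B, 8 of 35 splits gave at least the 1425 genes at an unadjusted p under 0.05 that the labels gave, and the highest other gave 2288, so chance is not excluded.

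At the same unadjusted threshold, chance is not excluded for the other results. For the experiment difference 16 of 100 splits reached the 737 genes of the labels (highest other 6060), and for the experiment difference in the MMP3 effect 6 of 99 reached 1620 (highest other 4734); both highest splits point to a structure of the samples. With densities shuffled within agent and experiment, 7 of 100 arrangements reached the 1358 genes of the density slope (highest other 2541), 53 the 228 of the interaction (highest other 4101), 14 the 490 of the slope in control cells (highest other 1205) and 36 the 1087 of the slope in MMP3 cells (highest other 3794).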
